A study of Danio rerio with 8 samples.

How the data were processed

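Whole zebrafish embryos (Danio rerio, wild type, AB strain) were given 3 µM E64d or DMSO between 1 and 24 hpf, after the chorion was nicked, and total RNA was taken from 4 pools of 7 embryos per group. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V8 kit. The authors deposited raw read counts per gene, 1 column per library. Per the submitters' processing notes, the tools were FastQC 0.12.1, Trim Galore 0.6.10, STAR 2.7.10b and featureCounts 2.0.6 with the build GRCz11. The annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart, and reads of near-identical copies (apobb.1 and apobb.2, or the cathepsin L genes) may have been split or dropped.

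The table held 36109 entries named by gene symbol, of which 5162 had a count of 0 in all 8 libraries. Columns were matched to samples by the column names that the labels give. A further 6 columns without a sample name were not used. Libraries held 29422983 to 37309883 counts. In each library, 75.9% to 80.7% of the counts from 1 to 20 were even, the pattern that arises where both mates of a read pair are counted, so a count may stand for less than 1 independent fragment. For this reason the tests were also run on counts divided by 2 and rounded up. That alternative, and the replicate block together with an estimated correlation, were chosen after seeing the data. PCR duplicates were not marked in these data, so counts are not independent molecules. The errors and intervals given measure the spread between pools or between the members of a list. Intervals of list medians treat the members as independent and may be too narrow where members move together.

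Groups and replicate numbers came from the sample titles. Counts were tested with edgeR 4.0.16 (R 4.3.3): genes were kept by filterByExpr at its defaults, libraries were scaled by TMM, and the groups were compared by the quasi-likelihood test with Benjamini-Hochberg adjustment over 22163 genes, at an adjusted p under 0.05. All adjusted p-values of genes are from that test unless another tool is named. CPM values are counts scaled to the TMM-adjusted library total. Errors of log2 fold changes are standard errors derived from the test statistic. The common biological coefficient of variation was 20%. Totals were compared by 2-sided exact permutation tests, whose smallest possible p with 4 against 4 is 0.0286.

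The gene lists, the rule for the genes to be named and all alternatives below except those described as chosen after seeing the data were set before the data were examined. There were 36 lists with 1267 entries. Of these, 1193 matched an entry of the table by their own name and 21 by a unique synonym in the RefSeq gene table of the assembly GRCz12tu, which was used for names only; 9 were second names of a member and 44 had no match. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 36 lists, and with an estimated correlation and fry beside it. Camera called 14 lists (7 upward, 7 downward), of which 4 held with an estimated correlation: the unfolded protein response, plasma proteins, lipoprotein assembly, and cathepsins. Fry, which asks whether a list's genes move one way without comparing them with other genes, called 19. Members tested again with adjustment within their own list are described as adjusted over the list alone.

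The rule for genes to be named took the 10 largest called changes in each direction among genes whose groups did not overlap, with a mean of at least 1 CPM in the higher group and a name that is not a clone's. It added 13 genes of the study's subject (hnf4a, hnf4b, hnf4g, apobb.1, mttp, apoa1a, apoa2, apoeb, ctsla, ctsba, ctsd, ctslb and sqstm1). From each called list it took the 2 risers and 2 fallers with the smallest p, and from each other list with a called member the 1 with the smallest p. The rule gave 81 genes. The results of 1 gene and 1 list are not reported here.

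Whether replicate numbers pair the libraries was checked on the deviations of each library from its group mean, by the rule that all 4 same-number correlations must exceed 0.1. Same-numbered libraries correlated at 0.113 to 0.379 across genes and others at −0.21 to 0.0555, and all 8 libraries correlated best with their own number. The numbers were therefore taken to pair the libraries. The pairing comes from the data, since the labels do not say what a number marks.

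The tests were checked on simulated data. Changes were given only to genes with a mean count above 20, with no pairing of libraries and no correlation between genes. For E64d against DMSO, 4 against 4, with 21719 genes, edgeR recovered 46% of genes changed 1.5-fold, 64% of those changed 2-fold, 94% at 4-fold and 100% at 8-fold, with 8.48% false calls. False calls were 21.5% with DESeq2 and 5.66% with limma-voom. On simulated lists over 21741 genes, camera called 2 of 2 lists shifted by 0.5 on the log2 scale and 0 of 41 unshifted ones, and fry called 0 of the 41. These simulated lists do not test whether the preset correlation of camera suits the real lists. In the real lists the estimated correlation ran from −0.0643 (hatching gland) to 0.686 (erythroid cells). Of the 14 lists called at the preset correlation, 4 held with an estimated one. Alternatives were RLE, upper-quartile and no scaling beyond totals, no filter and a filter of at least 10 counts in every library, DESeq2 1.42.0, limma-voom, a robust dispersion, the replicate block, 1 surrogate variable (sva 3.50.0), the removal of the 20 most abundant genes, a minimum log2 fold change of 1, and the omission of each library in turn. No reference genome was used, so no coordinates are given. Figures were drawn with matplotlib.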

Results

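The study asked how blocking cysteine proteases from early cleavage onward changes gene expression in the zebrafish embryo. The title of the series concerns the mobilization of yolk lipid, growth after segmentation, and an axis of Hnf4 and lipoproteins. Wild-type embryos of the AB strain were kept in 3 µM E64d, a cell-permeable inhibitor of cysteine proteases, or in the solvent dimethyl sulfoxide (DMSO, stated as 0.5% for both groups). Treatment began 1 hour after fertilization and ended at 24 hours (24 hpf). RNA of whole embryos was sequenced. Each of the 2 groups had 4 biological replicates, and each replicate was a pool of 7 embryos, so the spread between libraries is the spread between pools.

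The deposited table held counts for 36109 genes in 8 libraries. The DMSO libraries 1 to 4 held 31874125, 36981105, 33510624 and 33185382 counts, and the E64d libraries 1 to 4 held 30149121, 33289015, 37309883 and 29422983. The group means of these totals differed by less than the spread between replicates (2-sided exact permutation test, p = 0.6). Within a group, log2 levels of libraries correlated across genes at 0.963 to 0.98, and no 2 libraries agreed within sampling noise. The first principal component, with 27.1% of the variance, put all E64d libraries on one side and all DMSO libraries on the other. DMSO replicate 2 lay farthest out on it, and it had the lowest share of mitochondrial counts (0.847%, against 1.27% to 1.97% in the other libraries).

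**Figure D1:**
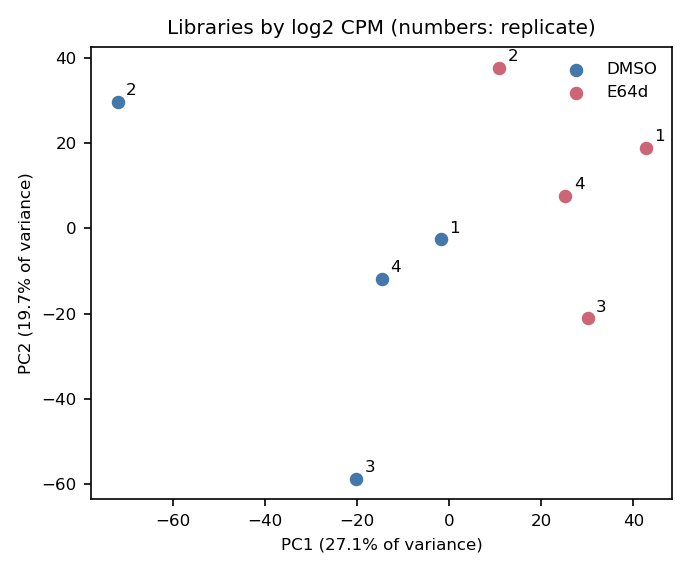
Scores of the 8 libraries on the first and second principal components of log2 CPM, coloured by group and numbered by replicate. The first component (27.1% of the variance) separates the groups, and DMSO replicate 2 has the most negative score (−72.1).

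After 23 hours in E64d, embryos carried more mRNA for chaperones of the endoplasmic reticulum and for several lipid enzymes, and less mRNA for cathepsins, for secreted plasma proteins and for a part of the lipoprotein machinery. The gene with the largest called rise was isg15, which encodes a ubiquitin-like protein best known from interferon responses, at 0.122 ± 0.0867 CPM (counts scaled to a common library total; SD, n = 4) in DMSO and 32.3 ± 12.2 CPM in E64d. The DMSO libraries held only 2 to 8 isg15 counts each, so the size of that rise is imprecise. The rise of derl3, a component of the pathway that clears misfolded proteins from the endoplasmic reticulum, went from 5.85 ± 0.457 to 152 ± 26.9 CPM (log2 fold change 4.70 ± 0.13 SE). Among the steepest falls was mttp, the microsomal triglyceride transfer protein that loads lipid onto apolipoprotein B, from 70.7 ± 5.66 to 9.73 ± 1.51 CPM (log2 fold change −2.86 ± 0.12 SE, adjusted p = 4.3e-08 by edgeR).

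Of 22163 genes tested, 1359 differed between the groups, 506 higher and 853 lower in E64d, and 304 of these changed by a log2 fold change of at least 1 (165 higher, 139 lower). In 1328 of the called genes the 4 values of one group lay wholly above those of the other, as they did in 14.4% of all tested genes, against 2.86% by chance. The other genes of the largest called rises were tmem86b (with 0 to 10 counts in each DMSO library), tnfb, ush1c, pmt, clstn3, trpc2a, dnajb9b and abcc12. Their log2 fold changes lay between 3.58 for abcc12 and 5.61 for tmem86b. Without DMSO replicate 1 the value of tmem86b was 7.62, and without E64d replicate 4 that of tnfb was 3.43. tnfb encodes a tumour necrosis factor, clstn3 a calsyntenin, and dnajb9b an Hsp40 co-chaperone of the endoplasmic reticulum. clstn3 rose from 7.86 ± 1.43 to 115 ± 28.2 CPM and pmt from 2.56 ± 0.737 to 41.4 ± 8.18 CPM. The other genes of the largest called falls were cyp11a1, the enzyme that opens steroid synthesis from cholesterol, the cathepsin gene ctss2.1, ebi3, sardh, anxa2b, slc10a1, dao.1, acot17 and rdh5. Their log2 fold changes lay between −3.09 for cyp11a1 and −2.49 for rdh5. The value of rdh5 was −3.12 without E64d replicate 4, and that of ebi3 moved from −2.98 to −3.56 without E64d replicate 3. The sarcosine dehydrogenase gene sardh fell from 95.8 ± 2.82 to 13.6 ± 5.67 CPM, and slc10a1, a bile acid transporter, from 9.99 ± 1.87 to 1.67 ± 0.506 CPM. The rise of tnfb and the fall of cyp11a1 did not pass with limma-voom (adjusted p = 0.245 and 0.0538).

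The replicate numbers were taken to pair the libraries from their correlations, while the main test leaves the pairing out. Calls and errors given without mention of the block therefore ignore it. With the number as a block 2580 genes were called (1040 higher, 1540 lower), among them all 1359. Scaling by library totals alone gave 1301 genes with 803 higher and 498 lower, a share of higher genes of 61.7% in place of 37.2%. The count fell to 835 without DMSO replicate 3 and to 834, 845, 854 and 655 without E64d replicates 1, 2, 3 and 4. It was 1234 without DMSO replicate 2, the library that stood apart. DESeq2 called 2207 genes.

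**Figure D2:**
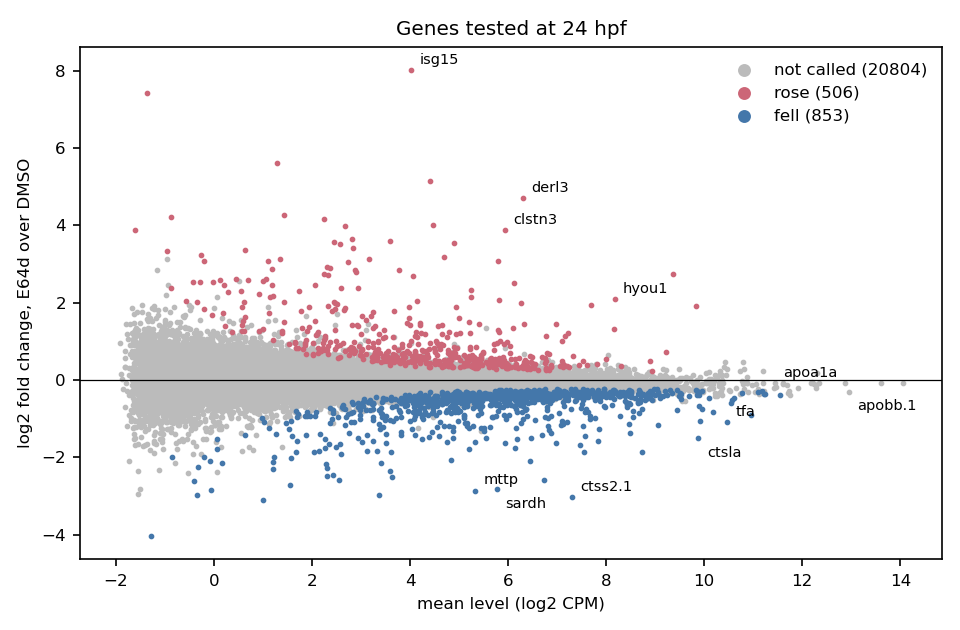
Log2 fold change (E64d over DMSO) against mean level (log2 CPM) for the 22163 tested genes, one point per gene, with 506 called higher in red and 853 called lower in blue. Most called genes lie within 1 log2 unit of 0, while isg15, derl3 and clstn3 stand far above the rest at their level and mttp, sardh and ctss2.1 far below.

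Genes for proteins that the yolk cell and liver secrete into plasma fell as a group. Of 31 tested members 18 fell and 1, the angiotensinogen gene agt, rose from a level near the floor (0.145 ± 0.0311 to 1.41 ± 0.891 CPM). The call of agt did not hold with limma-voom (adjusted p = 0.0719), and 1 of the 36 listed genes is also in another list. The transferrin gene tfa fell from 1929 ± 322 to 904 ± 51.4 CPM (log2 fold change −1.09 ± 0.10 SE) and the antiprotease gene serpina1l from 155 ± 9.99 to 68.4 ± 8.46 CPM (−1.18 ± 0.09). The median log2 fold change of the list was −0.66, and 20 members fell when adjusted over the list alone. The list stood below other genes by camera (adjusted p = 1.3e-22, and adjusted p = 0.00252 with an estimated correlation), a call lost with both the replicate block and an estimated correlation (adjusted p = 0.126).

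Genes of lipoprotein assembly and apolipoproteins moved apart. Of 21 tested members 10 fell and 2 rose (11 and 3 when adjusted over the list alone), with a median of −0.29. The fall of mttp was the largest. apoc2, the cofactor of lipoprotein lipase, fell from 186 ± 26.5 to 83.2 ± 6.01 CPM (−1.16 ± 0.10), and apoeb and apoa2 fell by 0.32 ± 0.07 and 0.29 ± 0.07 on the log2 scale. The most abundant member, apobb.1, which encodes an apolipoprotein B, stood at 8740 ± 1103 and 7114 ± 1022 CPM and did not pass (−0.30 ± 0.11, adjusted p = 0.14). It passed with the replicate block (adjusted p = 0.00377). Its copy apobb.2, named after its values were seen, fell from 190 ± 26.9 to 61.1 ± 20.6 CPM. Reads that fit both copies could have been split between them or dropped. apoa1a, an apolipoprotein A-I gene, stood at 2855 ± 142 and 2707 ± 113 CPM (−0.08 ± 0.06, adjusted p = 0.564; 0.01 under library totals alone). The risers were zgc:85843, listed as tm6sf2a (45.8 ± 13.5 to 84.8 ± 13.3 CPM), and surf4l, a cargo receptor for secretion (102 ± 9.73 to 133 ± 15.4 CPM). Camera placed the list below other genes (adjusted p = 2e-11, and adjusted p = 0.00385 with an estimated correlation), a call lost with both the replicate block and an estimated correlation (adjusted p = 0.246). Leaving out single libraries ended the calls of apoa2 (without DMSO replicates 3 or 4 or E64d replicates 1, 2 or 4, adjusted p up to 0.127, and 0.112 under library totals alone), apoeb (without E64d replicates 2, 3 or 4, up to 0.0955) and surf4l (without DMSO replicates 3 or 4 or E64d replicates 1, 3 or 4, up to 0.0943).

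hnf4a, the nuclear receptor gene named in the series title's axis, stood at 7.45 ± 1.46 CPM in DMSO and 4.49 ± 1.80 CPM in E64d (log2 fold change −0.73 ± 0.26, adjusted p = 0.126). It passed with the replicate block (−0.78, adjusted p = 0.00998), with DESeq2 (adjusted p = 0.0488) and without E64d replicate 2 (adjusted p = 0.0371). hnf4b stood at 20.4 ± 2.02 and 19.6 ± 2.39 CPM (adjusted p = 0.85) and hnf4g at 1.19 ± 0.378 and 1.55 ± 0.443 CPM (adjusted p = 0.618). Of the 16 tested members of the list of hnf4 genes and partner transcription factors, 3 rose: cebpb (0.47 ± 0.09), gata6 (0.41 ± 0.09) and foxa3 (0.44 ± 0.12). There were 5 up and 2 down when adjusted over the list alone. Without DMSO replicate 3, E64d replicate 1 or E64d replicate 2, 1 member rose, and with the replicate block 2 fell. Of the 18 listed genes, 6 are also in another list. The list's call toward higher levels (adjusted p = 0.0331) was lost with an estimated correlation (adjusted p = 0.255 with an estimated correlation), with the replicate block (adjusted p = 0.0575), and without DMSO replicate 3 or E64d replicate 2 (adjusted p = 0.0809 and 0.0811). The calls of gata6 (without DMSO replicate 3 or E64d replicates 1 or 2, adjusted p up to 0.0609) and foxa3 (without DMSO replicates 1, 2 or 3 or E64d replicates 1, 2 or 4, up to 0.135, and 0.0539 with limma-voom) were lost as well, with log2 fold changes of 0.34 to 0.46 and 0.40 to 0.52 over the omissions.

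**Figure D3:**
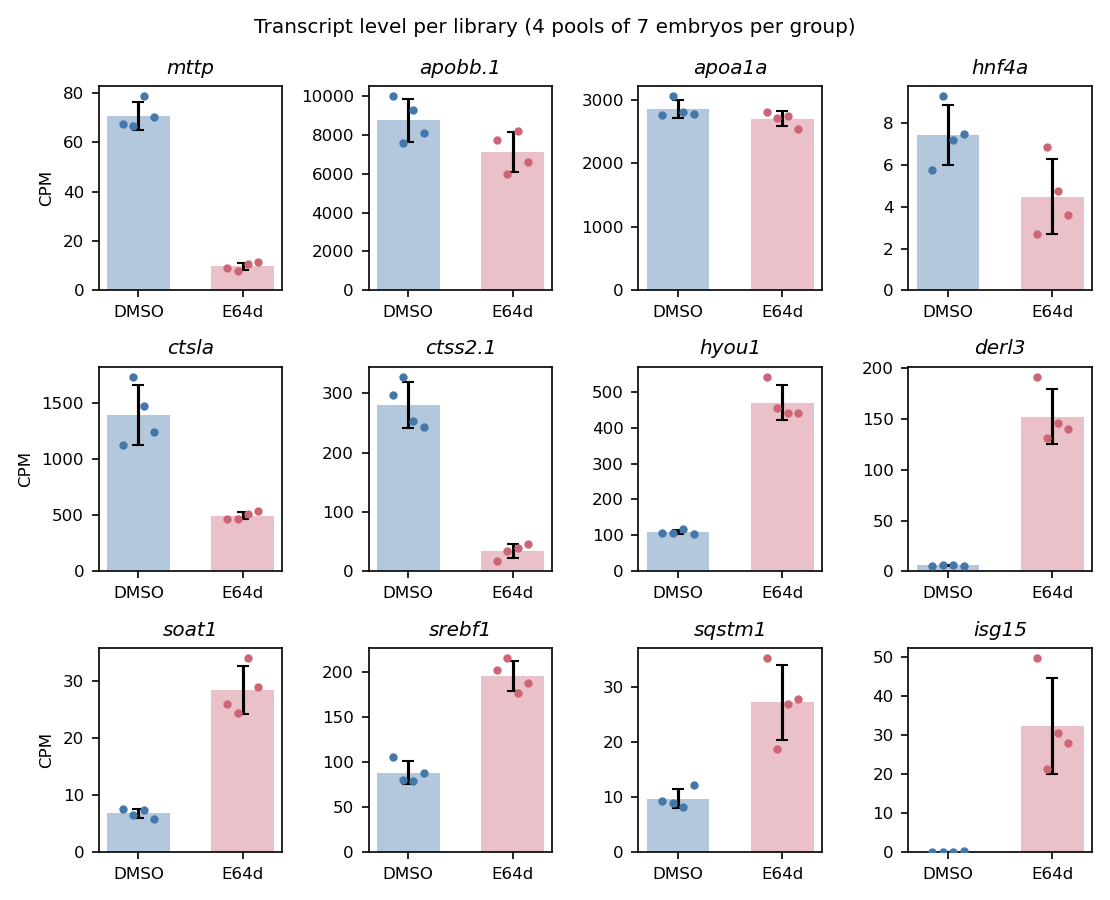
Level in CPM of 12 genes in each library, with bars for the mean and error bars for the SD of 4 libraries, for DMSO in blue and E64d in red. mttp, ctsla and ctss2.1 are lower and hyou1, derl3, soat1, srebf1, sqstm1 and isg15 higher in all E64d libraries than in any DMSO library, while the groups overlap for apobb.1, apoa1a and hnf4a. Within every same-numbered pair, apobb.1 and hnf4a are lower in the E64d library, which does not hold for apoa1a.

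Several enzymes of lipid storage and synthesis rose while several transport and oxidation genes fell. soat1, which esterifies cholesterol for storage, rose from 6.83 ± 0.819 to 28.3 ± 4.21 CPM (log2 fold change 2.05 ± 0.13). The gene plin2, a coat protein of lipid droplets named after its values were seen, rose from 11.7 ± 4.64 to 99.1 ± 26.0 CPM (3.08 ± 0.25). Of 33 tested members of lipid uptake, transfer and storage, 8 rose and 7 fell (12 and 8 when adjusted over the list alone). The list was not called by camera (adjusted p = 0.0928). It was called upward by fry (adjusted p = 0.00231), and by camera with the replicate block (adjusted p = 0.00786), with counts divided by 2 (adjusted p = 0.042), and without DMSO replicates 1 or 2 or E64d replicates 1 or 3 (adjusted p = 0.0215, 0.0428, 0.0484 and 0.0388). With an estimated correlation it was not called (adjusted p = 0.204, and 0.246 with the replicate block as well). With the block 13 members rose. soat2, also named after its values were seen, fell from 19.0 ± 2.31 to 5.23 ± 1.5 CPM.

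In cholesterol synthesis 7 of 26 members rose and 3 fell (10 and 3 when adjusted over the list alone), and 4 rose without DMSO replicate 1, E64d replicate 3 or E64d replicate 4. hmgcra, the gene of the rate-limiting reductase, rose from 2.23 ± 0.798 to 8.80 ± 1.91 CPM and hmgcs1 from 31.7 ± 3.36 to 47.4 ± 4.33 CPM. acat2 fell from 45.9 ± 2.89 to 34.5 ± 0.877 CPM. In fatty acid and glycerolipid synthesis 7 of 35 rose and 3 fell (12 and 7 when adjusted over the list alone), and 5 fell with the replicate block. srebf1, a master regulator of lipid synthesis, rose from 88.5 ± 12.6 to 196 ± 16.9 CPM and the desaturase gene scd from 2.29 ± 0.511 to 9 ± 1.89 CPM. acsl1b fell from 202 ± 9.56 to 94.5 ± 14.1 CPM, and lpin1 from 7.53 ± 0.994 to 3.85 ± 0.589 CPM. In fatty acid oxidation 6 of 36 members fell (8 when adjusted over the list alone, and 3 without E64d replicate 4), among them cpt1ab, which admits fatty acids to mitochondria (−0.63 ± 0.10), and hadhab (−0.39 ± 0.07). The other 30 did not pass. Camera called the cholesterol list (adjusted p = 0.00272, and adjusted p = 0.166 with an estimated correlation) and the fatty acid synthesis list upward (adjusted p = 0.0292, and adjusted p = 0.362 with an estimated correlation). It called the oxidation list downward (adjusted p = 0.00848, and adjusted p = 0.214 with an estimated correlation). The call of the fatty acid synthesis list ended without DMSO replicates 2, 3 or 4 or E64d replicate 3 (adjusted p = 0.0586, 0.0635, 0.0624 and 0.053) and by fry (adjusted p = 0.0531).

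The unfolded protein response, the program that a load of misfolded protein in the endoplasmic reticulum switches on, rose nearly as a whole. Of 27 tested members 22 rose and 5 did not pass, with a median log2 fold change of 1.02 (23 up and 1 down when adjusted over the list alone). The chaperone gene hyou1 rose from 109 ± 6.60 to 469 ± 48.4 CPM (2.1 ± 0.08) and the co-chaperone gene dnajc3a from 13.8 ± 1.91 to 61.4 ± 5.58 CPM (2.15 ± 0.11). Of members named after their values were seen, hspa5, the chaperone BiP, rose from 379 ± 39.7 to 1435 ± 187 CPM and hsp90b1 from 171 ± 35.8 to 1147 ± 161 CPM. The stress factor gene ddit3, named in the same way, rose from 17.1 ± 3.10 to 37 ± 3.15 CPM. Camera placed the list above other genes (adjusted p = 1e-105, and adjusted p = 0.00252 with an estimated correlation). The call was lost with both the replicate block and an estimated correlation (adjusted p = 0.0952), and 22 members rose without DMSO replicate 2.

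Of 30 members of the list of amino acid starvation and atf4 targets 5 rose and 1 fell (7 and 1 when adjusted over the list alone). sesn2 rose from 7.09 ± 0.507 to 15.2 ± 1.56 CPM and cth, an enzyme of cysteine synthesis, from 42.4 ± 3.88 to 83.3 ± 12.0 CPM. The gene slc3a2a, the heavy chain of amino acid transporters, fell from 161 ± 33.9 to 66.2 ± 3.64 CPM. The list's call (adjusted p = 0.034) was lost with an estimated correlation (adjusted p = 0.313 with an estimated correlation), with the replicate block (adjusted p = 0.0663), and without DMSO replicates 1 or 4 or E64d replicate 3 (adjusted p = 0.067, 0.149 and 0.0691).

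Several cathepsin genes, of the protease family that E64d inhibits, fell. Of 16 tested cathepsin and legumain genes 6 fell, and the other 10 did not pass (6 when adjusted over the list alone). Of the 17 listed genes, 4 are also in another list. ctss2.1, a cathepsin S gene, fell from 280 ± 39.5 to 34.4 ± 12.1 CPM (log2 fold change −3.03 ± 0.23), ctsla, a cathepsin L gene, from 1394 ± 268 to 495 ± 31.6 CPM (−1.49 ± 0.12) and ctsba, a cathepsin B gene, from 484 ± 51.3 to 219 ± 26.3 CPM (−1.14 ± 0.10). ctsc and ctsh, named after their values were seen, fell by 1.58 ± 0.13 and 1.11 ± 0.10 on the log2 scale. The aspartic protease gene ctsd fell by 0.31 ± 0.07 on that scale, and not without DMSO replicate 3 or E64d replicates 1, 2 or 4 (adjusted p up to 0.0971) or under library totals alone (adjusted p = 0.0863). ctslb stood at 256 ± 14.8 and 273 ± 11.1 CPM (0.10 ± 0.07, adjusted p = 0.48). Camera placed the list below other genes (adjusted p = 2.6e-12, and adjusted p = 0.0453 with an estimated correlation). That call was lost with both the replicate block and an estimated correlation (adjusted p = 0.246).

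Of 54 lysosomal genes other than cathepsins 9 fell and 3 rose (10 and 4 when adjusted over the list alone). The falls numbered 5 without E64d replicate 2, 4 without E64d replicate 4 and 5 under library totals alone. In the list 1 gene rose without E64d replicates 1 or 3. npc2, which carries cholesterol out of lysosomes, fell from 268 ± 17.8 to 83.2 ± 13.5 CPM (−1.69 ± 0.11) and the lipid-binding cofactor gene gm2a from 42.6 ± 5.58 to 20.3 ± 3.31 CPM. tfe3a, a regulator of lysosomal genes, rose from 35.3 ± 3.18 to 52.3 ± 5.19 CPM. The rise of galns, from 20.5 ± 1.47 to 27.4 ± 2.63 CPM, did not pass without DMSO replicate 1 or E64d replicates 1 or 3 (adjusted p up to 0.0881). The list's median was −0.03 and 0.05 under library totals alone. Its call downward (adjusted p = 0.022) was lost with an estimated correlation (adjusted p = 0.362 with an estimated correlation), under library totals alone (adjusted p = 0.0535) and without E64d replicate 2 (adjusted p = 0.0811).

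Of 37 autophagy genes 3 rose and 2 fell (12 and 2 when adjusted over the list alone). The list was called upward (adjusted p = 0.00518, and adjusted p = 0.122 with an estimated correlation). The rises numbered 10 under library totals alone, 9 with the replicate block, 8 with DESeq2, 7 with upper-quartile scaling, 5 without DMSO replicate 2 and 1 without E64d replicate 4. The receptor gene sqstm1, whose protein p62 is itself degraded by autophagy, rose from 9.75 ± 1.71 to 27.2 ± 6.76 CPM (1.48 ± 0.18) and the related nbr1a from 15.7 ± 0.255 to 21.3 ± 0.841 CPM. atg3 and atg4b, of the conjugation machinery, fell by 0.50 ± 0.09 and 0.38 ± 0.09 on the log2 scale. The calls of nbr1a (without E64d replicate 4, adjusted p = 0.0506) and atg4b (without DMSO replicates 3 or 4 or any E64d replicate, adjusted p up to 0.0861, and 0.0862 under library totals alone) were lost there, with log2 fold changes of 0.41 to 0.46 and −0.40 to −0.35 over the omissions. Of 23 calpain and cystatin genes 3 fell (3 when adjusted over the list alone). Among them, cst3, an extracellular inhibitor of cathepsins, fell from 142 ± 6.25 to 73.1 ± 5.29 CPM and capn2a from 203 ± 20.6 to 150 ± 9.59 CPM. That list's call downward (adjusted p = 0.034) was lost with an estimated correlation (adjusted p = 0.171 with an estimated correlation), with the replicate block (adjusted p = 0.0708) and under library totals alone (adjusted p = 0.0638). It was also lost without DMSO replicate 3 or E64d replicate 2 (adjusted p = 0.0836 and 0.0641).

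**Figure D4:**
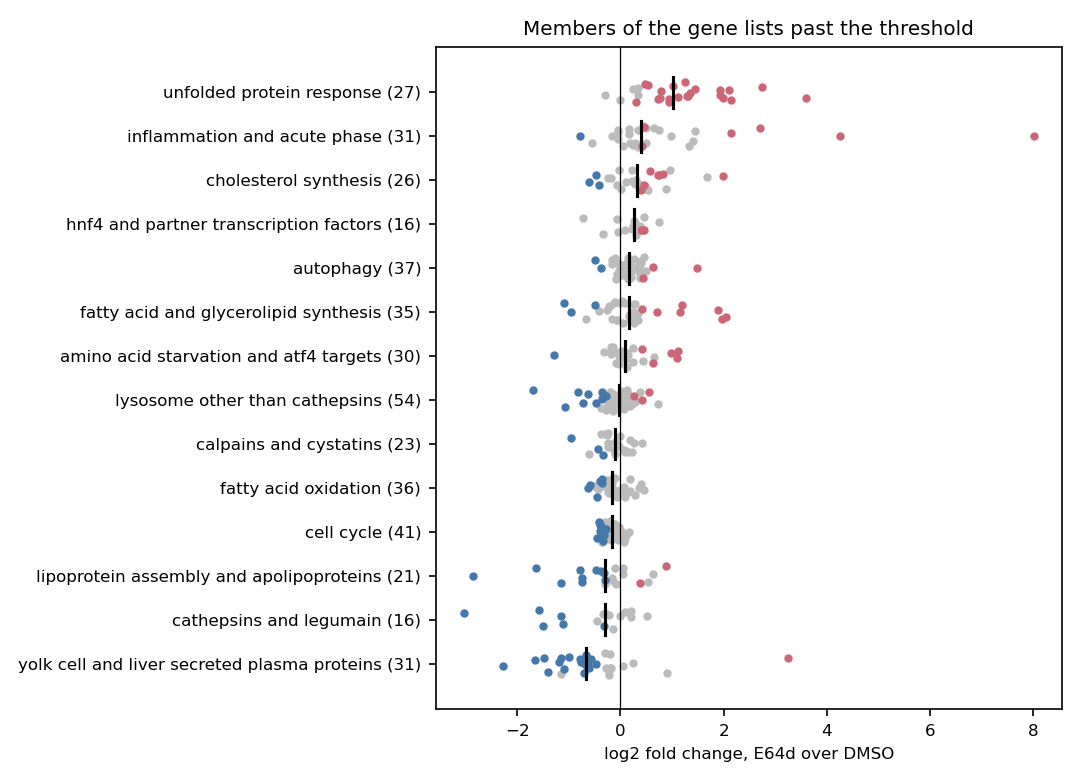
Log2 fold change (E64d over DMSO) of each tested member of the 14 lists called by camera, one row per list with the number of members in brackets, red for members that rose, blue for members that fell, grey for members that did not pass, and a black bar at the median. The unfolded protein response list (median 1.02) lies almost wholly above 0 and the plasma protein list (median −0.66) mostly below, while the other medians lie within 0.5 log2 units of 0.

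Of 31 genes of inflammation and the acute phase 6 rose and 1 fell (12 and 1 when adjusted over the list alone), and 3 rose with limma-voom. Besides isg15, tnfb rose from 0.26 ± 0.0634 to 5.05 ± 4.81 CPM (log2 fold change 4.26, and 3.43 without E64d replicate 4) and stat3 from 52.7 ± 2.48 to 70.9 ± 4.93 CPM. The complement gene c3a.1 fell from 473 ± 52.5 to 274 ± 15.4 CPM. The call upward (adjusted p = 1.3e-05) was lost with an estimated correlation (adjusted p = 0.255 with an estimated correlation). Of 41 cell cycle genes 9 fell by 0.27 to 0.44 on the log2 scale and 32 did not pass (16 fell when adjusted over the list alone). The falls numbered 1 without DMSO replicate 3, 2, 4 and 3 without E64d replicates 1, 2 and 3, 4 under library totals alone, 14 with DESeq2 and 15 with the replicate block. Without E64d replicate 4, edgeR called 0 and 17 had an unadjusted p under 0.05. The replication genes mcm5 and pcna fell from 452 ± 41 to 350 ± 15.7 CPM and from 948 ± 134 to 713 ± 23.6 CPM. The list was called downward (adjusted p = 1.2e-05, and adjusted p = 0.204 with an estimated correlation). The call of mcm5 ended without E64d replicate 4 (adjusted p = 0.0565), and that of pcna without DMSO replicate 3 or E64d replicates 1 or 4 (adjusted p up to 0.0764).

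Other lists of stress and metabolism described here were not called by camera, whose adjusted p is given for each, while fry called insulin signalling upward and heat shock downward (adjusted p = 0.00697 and 0.00402). In insulin signalling 5 of 37 rose and 1 fell (8 and 1 when adjusted over the list alone; list adjusted p = 0.0928, but 0.0429 under library totals alone). The binding protein gene igfbp1a rose from 6.36 ± 0.984 to 15.6 ± 3.18 CPM. The rises there numbered 3 without E64d replicates 1 or 3, 2 without E64d replicate 4 and 9 with the replicate block. In glycolysis 1 of 35 rose and 4 fell (2 and 4 when adjusted over the list alone; list adjusted p = 0.1), and pgam1a fell by 0.81 ± 0.12 on the log2 scale. The list was called without DMSO replicate 1 or E64d replicate 4 (adjusted p = 0.0171 and 0.0365), while 2 members fell without DMSO replicate 3 or E64d replicate 4. In the hypoxia response 1 of 25 rose and 1, epas1a, fell by 0.61 ± 0.07 on that scale (3 and 1 when adjusted over the list alone; list adjusted p = 0.099, but 0.0484 without E64d replicate 1), and 3 rose with the replicate block. In the oxidative stress response 1 of 27 rose, which was sqstm1, and 5 fell (4 and 6 when adjusted over the list alone; list adjusted p = 0.264). There were 3 falls without E64d replicate 4 or under library totals alone and 3 rises with the block. Of 25 heat shock genes 2 fell (2 when adjusted over the list alone), among them hspa4a (−0.53 ± 0.08), and the list was not called by camera (adjusted p = 0.238). Of 22 xenobiotic response genes 1 rose and 2 fell (4 and 4 when adjusted over the list alone; list adjusted p = 0.889), and cyp1c1 fell from 9.09 ± 3.28 to 1.64 ± 0.301 CPM. In that list 5 rose with the block and 3 without DMSO replicate 3, and its median was 0.04 and its mean −0.03.

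Few markers of embryonic tissues were called. That does not exclude small changes, since edgeR recovered 46% of genes changed 1.5-fold in the simulations. Those simulations changed only genes above a set mean count, so the share for markers at lower levels is not known. In 7 lists, for skeletal muscle, heart, erythroid cells, endothelium, notochord, lens and retina, and the segmentation clock, edgeR called 0 of 232 tested members, 32 had an unadjusted p under 0.05, DESeq2 called 4, limma-voom 0 and edgeR with the replicate block 14. Their medians lay between −0.07 and 0.10, and that of heart was 0.01 with a mean of −0.15. Camera called none of these 7 lists (adjusted p = 0.132 for endothelium, 0.262 for segmentation, 0.366 for notochord and for lens and retina, 0.468 for muscle and for heart, and 0.973 for erythroid cells). Muscle was called without DMSO replicate 1 (adjusted p = 0.0379, with 2 members down) and the erythroid list without E64d replicate 1 (adjusted p = 0.0484). In the myeloid list 2 of 33 members fell, ctss2.1 and the apolipoprotein gene apoc1 (named after its values were seen), which are also in the cathepsin and lipoprotein lists (2 when adjusted over the list alone; list adjusted p = 0.108). Of 36 listed myeloid genes 6 are in another list. Of 40 genes of pigment cells and neural crest 1 rose and 3 fell (2 and 3 when adjusted over the list alone; list adjusted p = 0.634), and 3 rose with the block. There paics, an enzyme of purine synthesis, fell from 519 ± 95.3 to 200 ± 11.1 CPM. In the epidermis list 1 of 47 rose and 1, the keratin gene cyt1, fell by 0.39 ± 0.07 on the log2 scale (1 and 1 when adjusted over the list alone; list adjusted p = 0.634), against 4 and 4 with the block. Among neural genes 1 of 56, tubb5, fell by 0.36 ± 0.07 on that scale (1 when adjusted over the list alone; list adjusted p = 0.328), against 3 up and 3 down with the block. In the endoderm list 1 of 26, foxa3, rose (0 when adjusted over the list alone; list adjusted p = 0.0928). In the hatching gland list 1 of 12, cd63, rose by 0.26 ± 0.07 (1 when adjusted over the list alone; list adjusted p = 0.247), and 4 rose with the block. In the list of germline and maternal transcripts 1 of 28, ccnb1, fell by 0.34 ± 0.08 on the log2 scale (2 when adjusted over the list alone; list adjusted p = 0.248), against 3 with the block. The calls of cd63 (without DMSO replicates 3 or 4 or any E64d replicate, adjusted p up to 0.129) and ccnb1 (without DMSO replicate 3 or E64d replicates 1, 2 or 4, up to 0.0896, and 0.0609 under library totals alone) were lost there, with log2 fold changes of 0.23 to 0.28 and −0.39 to −0.30 over the omissions. Fry called the myeloid list downward (adjusted p = 0.0411) and the endoderm and hatching gland lists upward (adjusted p = 0.00697 for each).

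The labels give the control 0.5% DMSO and describe this as the level of the E64d group. By the listed dilutions alone, 3 µM from a 10 mM stock carries 0.03% DMSO, and the labels used here do not say whether DMSO was added to make up the difference.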

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

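All 6 tests of explanations here were chosen after the results were seen, except that the count of splits was planned in advance; its prediction too was written afterwards.

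The library values and the CPM of the named genes were searched for single libraries far from the other 3 of their group. In 170 groups of 4, 5 had such a library, where chance gives about 8.5. They were apoa2 in E64d replicate 3 (942 CPM, the others 795 to 812), tfa in DMSO replicate 2 (2408 CPM, the others 1734 to 1825), hyou1 in E64d replicate 1 (541 CPM, the others 441 to 453), epas1a in E64d replicate 2 (86.3 CPM, the others 93.6 to 94.4) and paics in DMSO replicate 2 (660 CPM, the others 457 to 487).

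Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many as 1359 called genes, and the highest of the others gave 1. That makes chance a less likely origin of the count but does not exclude it. The other splits mix E64d and DMSO libraries, so a difference between the groups widens their spread and lowers their counts. Of the 8 splits that part all 4 pairs, the real one gave 1359 genes and the highest other 0. If the libraries are paired, only these 8 can be compared, too few to exclude chance.

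The unfolded protein response list rose together. The scaling factors differ between the groups, being above 1 in all E64d libraries and below 1 in all DMSO libraries. A factor of this kind moves all genes of a library alike, yet the list's median lay 1.01 above that of all tested genes (95% interval 0.52 to 1.43), which argues against scaling as the cause. The interval treats the 27 members as independent, though their estimated correlation was 0.286, so it may be too narrow. The labels describe 0.5% DMSO as matched between the groups, but the listed dilutions alone carry 0.03% into the E64d wells, so if those were not topped up the control had 16.7 times as much, a difference that stays open as untested and confounded with the groups. A response to the inhibitor stays open as the biological hypothesis that the design names.

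The genes of secreted plasma proteins and lipoproteins fell. A smaller share of the secreting tissue in the E64d pools cannot be told apart: the log2 fold changes of the 52 members varied 23.6 times more than their errors allow for 1 shared factor (Cochran's Q over its degrees of freedom, 95% point 1.35), but it is not known which members are made in that tissue alone, and those with other sources would fall less. A delay in development cannot be told apart either. The muscle list, a later tissue, had a median of −0.068 (95% interval −0.10 to 0.01) and the segmentation list one of 0.09 (−0.01 to 0.17). Both medians lie on the side that a delay predicts, but both intervals include no change. Camera called the muscle list downward in 1 of 8 omissions (without DMSO replicate 1, adjusted p = 0.0379). In the absence of a time series it is not known how far a delay would move each list. A solvent difference, if the wells were not topped up, stays open here as well, untested. A lower expression of these genes under E64d stays open as the biological hypothesis.

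The cathepsin genes fell. Fewer myeloid cells would lower other myeloid markers by about the same amount as the 6 fallen cathepsins (median −1.32), but 30 markers outside the cathepsin and lipoprotein lists had a median of −0.0061 (95% interval −0.22 to 0.16), with lcp1, abundant among them, at 17.8 ± 3.82 and 14.5 ± 2.2 CPM. Reads moving between similar copies within the list would leave its sum in place. Yet the summed CPM of the list fell by 1.03 on the log2 scale, from 3361 ± 383 to 1644 ± 83.4. The sum does not cover reads that were dropped or that moved to genes outside the list. The markers concern myeloid cells alone. A smaller share of another tissue that expresses cathepsins, and a delay in development, stay open, as neither was tested for these genes. A solvent difference, if the wells were not topped up, stays open for this pattern too, untested. A fall of cathepsin transcripts in response to the inhibitor is a hypothesis that these tests leave open.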

How the results depend on the processing

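Counts divided by 2, and the replicate block together with an estimated correlation, were chosen after seeing the data. The 1359 genes (506 higher, 853 lower) became 2580 (1040, 1540) with the replicate block, 2207 (854, 1353) with DESeq2, and 304 (165, 139) at a minimum log2 fold change of 1. The count was 1301 under library totals alone, but with 803 higher and 498 lower; the median of all genes moved by 0.0855. Omitting 1 library gave 655 to 1396 genes, 288 to 560 higher and 367 to 836 lower. The count was 1396, 1234, 835 and 1265 without DMSO replicates 1, 2, 3 and 4, and 655 to 854 without single E64d replicates. The part played by the smaller number of samples was not tested. Other settings gave 1285 to 1627 genes. No gene called in the main test was called in the opposite direction under any setting. The replicate block kept all 1359 calls; among named genes it added hnf4a and apobb.1, among lists it added lipid uptake and ended 3 (hnf4 partners, atf4 targets, calpains), and it changed no other such call. Of 14 lists called, 4 remained with an estimated correlation, and 0 with the block as well, where few degrees of freedom are left (12 with the block alone, 19 by fry). Under omissions 11 to 17 lists were called.

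Of 81 named genes, 61 kept direction and side in every setting in which they were compared. The robust dispersion, the surrogate variable, the removal of the 20 most abundant genes and the minimum fold change were not applied to named genes. A gene without a value in a setting was skipped there. Directions turned for hnf4b (0.030 under library totals alone, 0.0093 without DMSO replicate 1, −0.13 to 0.0093 over the omissions) and apoa1a (0.010 under library totals alone), neither of them called, and for the erythroid list (adjusted p = 0.0484 without E64d replicate 1, up to 0.739 over the omissions); the cause was not tested. Library totals of the groups differed by less than their spread with and without the 20 most abundant genes (exact permutation p = 0.6 in both). At 1.5-fold the simulations recovered 46% of changed genes, a share not split by level and drawn only from genes with a mean count above 20. Depth limits the fold of isg15, with 2 to 8 counts in each DMSO library.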

Other observations

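The gene groups here were drawn up after the values were seen. Of 28 groups screened, 27 had enough tested members. Where a group was assembled by hand from several symbols or prefixes, only its counts are given, since members already seen to change had a part in the choice. The ribosomal proteins are an exception, as genes of their large and small subunits differ in prefix. For the ribosomal proteins and for families that share 1 symbol prefix, p-values are adjusted over the 27 groups and describe these libraries. The omission of single libraries was not run.

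Several genes of purine synthesis, one-carbon metabolism and the pentose phosphate pathway fell. Of 14 genes of de novo purine synthesis, 4 of them also in a fixed list, 9 fell and 1 rose; among the falls were paics, from 519 ± 95.3 to 200 ± 11.1 CPM (SD, n = 4), gart, from 496 ± 91.6 to 256 ± 6.74 CPM, and pfas, from 410 ± 78.6 to 214 ± 8.72 CPM. Of 31 genes of one-carbon, sarcosine and creatine metabolism, 5 of them in a fixed list, 8 fell, with dmgdh down from 295 ± 56.1 to 81.8 ± 4.82 CPM, mthfd1b from 279 ± 44.5 to 102 ± 11.8 CPM and gatm, the first enzyme of creatine synthesis, from 1299 ± 144 to 624 ± 34.3 CPM. Under library totals alone 7 purine synthesis genes and 7 of these fell. Of 8 genes of the pentose phosphate pathway 4 fell, with tktb, a transketolase, down from 736 ± 44.5 to 331 ± 11 CPM. Of 24 complement genes 10 fell and 3 rose; cfh, a brake on complement, fell from 57 ± 10.2 to 16.4 ± 8 CPM, c9 fell from 101 ± 8.97 to 42.8 ± 9.54 CPM, and c7b rose from 12.6 ± 4.91 to 63 ± 14.7 CPM.

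Some subunits of large housekeeping complexes fell by small amounts. A bias of gene length or GC content was not tested for these. Of 40 proteasome genes 18 fell (median −0.26), such as psmb5 (194 ± 4.68 to 150 ± 7.82 CPM), and of 74 mitochondrial ribosomal genes 18 fell (median −0.29), such as mrpl12 (58.9 ± 6.71 to 43.9 ± 2.64 CPM). Of 19 ATP synthase genes 11 fell (median −0.31), such as atp5fa1 (1044 ± 102 to 798 ± 24.8 CPM), of 23 cytochrome c oxidase subunit and assembly genes 6 fell, and of 44 complex I genes 5 fell. In camera with an estimated correlation the mitochondrial ribosome and ATP synthase lists held (adjusted p = 0.0241 for each, but 0.125 for each with the replicate block as well), and the proteasome, cytochrome c oxidase and complex I lists did not (adjusted p = 0.0746, 0.0503 and 0.0531). Under library totals alone 11, 10, 7, 2 and 1 members fell in the proteasome, mitochondrial ribosome, ATP synthase, oxidase and complex I lists. Of 78 cytosolic ribosomal genes 1 fell (median −0.16, adjusted p = 0.443 with an estimated correlation). Of 20 subunits of the vacuolar proton pump 2 fell, atp6v0ca and atp6v1ab (adjusted p = 0.443 with an estimated correlation). Neither these falls nor that of the cytosolic ribosomal gene passed under library totals alone, where 1 subunit of the pump rose. Of 23 tubulin genes 2 fell, tuba8l4 and tubb5 (adjusted p = 0.0957 with an estimated correlation).

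Of 39 interferon-regulated genes and regulators 3 rose, isg15, irf3 (1.13 ± 0.575 to 8.63 ± 1.96 CPM) and irf1b (0.795 ± 0.22 to 3.55 ± 2.02 CPM), and 36 did not pass (median 0.05). Of 13 genes of the COPI coat and of ARF proteins, which act in vesicle traffic, 2 rose, arf4b from 0.44 ± 0.129 to 3.75 ± 0.654 CPM and arf4a from 84.3 ± 9.14 to 137 ± 14.1 CPM. Among 35 genes whose symbols begin with cyp2, cyp2aa9 fell from 60.4 ± 10.2 to 19.9 ± 5.14 CPM and its relative cyp2aa7 rose from 5.66 ± 2 to 19.6 ± 2.83 CPM; 5 fell and 1 rose in all (adjusted p = 0.0856 by camera and 0.0178 by fry). Of 36 conjugation enzymes 4 fell, ugt1b1, ugt1b5, ugt1b7 and ugt5a4. Of 20 disulfide isomerases and oxidases 3 rose and 2 fell, with pdia4 up from 86 ± 12.9 to 328 ± 41.6 CPM. Of 35 transporters with ATP-binding cassettes 2 rose and 2 fell, and of 136 solute carriers 5 rose and 15 fell. Under library totals alone 5 of the former rose and 1 fell, 9 of the latter rose and 11 fell, and among the isomerases and oxidases 3 rose and 1 fell. In the group with symbols beginning with cyp2, 2 rose and 5 fell under library totals alone.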
